A study of Mus musculus with 8 samples.

How the data were processed

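Total RNA of the left ventricle was measured by paired-end sequencing in 8 libraries: WT (n = 2), mdx (n = 3) and mdx sln+/- (n = 3), all from mice of 6 months, per the labels. Reads were aligned to mm10 with STAR 2.6.1, quantified and normalized in Partek and tested with limma, per the submitters' processing notes. The deposited values are log2 values per transcript, with 33027 transcripts of 14578 genes (12392 protein coding) in 16 value columns, an r1 and an r2 column for each library, per the file headers. That the deposited log2 values are log2(normalized abundance + 1) was inferred from the values, of which 0 lie at or under 0, the lowest is 3.07e-05 and the highest 16.2. Whether the abundances were divided by transcript length is not given, and no counts were used, so depth and the precision it gives are unknown. What r1 and r2 mean is not given either; they correlated at 0.981 to 0.987 within a library and were averaged to 1 replicate, so they are not counted as separate samples. All value columns were mapped to a library (0 unmapped).

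The log2 values were averaged over r1 and r2, turned back to linear abundances, summed over the transcripts of each gene and expressed as log2(value + 1). Genes with a value of at least 1 in at least 2 libraries were kept (13783), and 795 were left out. The design had been written for counts; because the unit is a normalized log2 value, its stated fallback, limma on log2(value + 1), was used. The model held the group only, with all 8 libraries in 1 fit, empirical Bayes with a prior that follows mean expression (limma 3.58.1, R 4.3.3; median prior degrees of freedom 2.96) and Benjamini-Hochberg adjustment with a threshold of 0.05 for each comparison. The comparisons were mdx against WT, mdx sln+/- against mdx and mdx sln+/- against WT.

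The deposited values hold the mark of an earlier correction. In every transcript the mean of mdx 2 and mdx sln+/- 2 equals the mean of mdx 1, mdx 3, mdx sln+/- 1 and mdx sln+/- 3, with a largest difference of 5.13e-05, while other choices of 1 library per group gave an SD of 0.127 to 0.199. A term with this contrast was thus removed before deposit, and the group fit counts 5 residual degrees of freedom where 4 are left, which makes its p-values too small. The number of called genes in each comparison is therefore given beside the number with that term fitted. Other counts come from the group fit unless the term is named.

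The design fixed 31 gene lists before the data were examined: extracellular matrix and fibrosis, cardiac stress and fetal programme, calcium handling, dystrophin-associated complex, sarcomere and cardiomyocyte, nuclear oxidative phosphorylation, mitochondrially encoded genes, fatty acid oxidation, glycolysis and glucose uptake, oxidative stress and antioxidant, unfolded protein response, autophagy and proteolysis, cardiac ion channels, interferon response, cell cycle, circadian clock, immediate early and heat shock, RNA without a poly(A) tail, sex-linked genes, and markers of macrophages, lymphocytes, neutrophils and mast cells, fibroblasts, endothelium, smooth muscle and pericytes, atrial myocytes, skeletal muscle, adipocytes, blood, nerve and Schwann cells, and mesothelium and valve. Lists with at least 3 measured members (26) were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, each adjusted over the lists. Counts adjusted over the list alone treat the members of 1 list at a time, without correction over the lists. The named genes follow a rule fixed with the lists. It names Dmd and Sln always, then, among called genes with a mean log2 value of at least 1 and no overlap between groups, without predicted-gene symbols, the 6 largest rises and the 6 largest falls, and then the 2 members of each list with the smallest adjusted p. With fewer than 4 called genes, the 4 highest and the 4 lowest by unadjusted p are given as values. Further genes with values were chosen after their values were seen.

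Overlap and covariance between comparisons that share libraries were set beside 100 draws of simulated libraries with no effect. Gene positions are those of GENCODE M21 (GRCm38/mm10). Transcripts that match mitochondrial genes were found with blastn 2.17.0 (at least 90% identity over at least 80% of the transcript), which gave 15. They are taken as nuclear copies, but reads of the mitochondrial genes themselves can be counted on them. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the values and figures. The fits and list tests were tested on simulated data with known changes first. There the group-only fit called 43 unchanged genes among 230 calls in mdx against WT, 27 among 205 in mdx sln+/- against mdx and 28 among 198 in mdx sln+/- against WT, more than the threshold allows. With the removed term fitted these were 14 among 181, 9 among 180 and 4 among 156. Alternatives tried were median-ratio and upper-quartile scaling, no filter and a mean value of at least 5, only the 2 groups compared, a replicate block, library name style as a term or only 1 name style, each library left out, the removed term, pseudocounts of 0.1 and 5, the leading transcript, r1 or r2 alone, rescaling without mitochondrial copies, Eif2s3y as a term, and the libraries with low Y-linked values left out.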

Results

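RNA from the left ventricle of 6-month-old mice was sequenced in 8 libraries of 3 genotypes. There were 2 wild-type (WT) libraries, 3 libraries of mdx mice, which lack the muscle membrane protein dystrophin through a mutation of Dmd, and 3 libraries of mdx mice that carry 1 functional copy of Sln (mdx sln+/-). Sln encodes sarcolipin, a small membrane protein that inhibits the calcium pump SERCA of the sarcoplasmic reticulum. The design asks how the mdx ventricle differs from WT and what the loss of 1 Sln allele changes in it. The deposited values are log2 abundances of 33027 transcripts, summed here to 14578 genes, of which 13783 were tested. Sequencing depth is unknown because the values are not counts, and the abundances of a library sum to between 780262 and 924253. The labels speak of mice but do not say which libraries came from separate animals, so p-values measure the spread between these samples. All log2 fold changes are on the log2(value + 1) scale, which understates changes of low genes. The error given after ± is the standard error from limma unless SD or another error is named. Genes given values outside the rule for named genes, such as Col3a1 and Ppargc1a, were chosen after their values were seen.

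Dmd, the mutated gene, was checked in every library first. Its log2 level was 6.60 and 6.98 in WT 1 and WT 2, 4.30, 4.32 and 4.22 in mdx 1, 2 and 3, and 4.09, 4.10 and 4.25 in mdx sln+/- 1, 2 and 3. The group means were 6.79 ± 0.26 in WT (SD, n = 2), 4.28 ± 0.05 in mdx (SD, n = 3) and 4.14 ± 0.09 in mdx sln+/- (SD, n = 3). Dmd thus fell by 2.51 ± 0.11 in mdx against WT, a level 5.70-fold lower (limma, adjusted p = 2.02e-05), and it was lower than WT in every library of both mdx groups. Dmd (ENSMUSG00000045103) lies on chromosome X from 82948870 to 85206141, plus strand (GRCm38/mm10, GENCODE M21, positions counted from 1). Its full-length transcript Dmd-203, with 79 exons, had a linear abundance of 90.8 ± 24.3 in WT, 11.8 ± 0.08 in mdx and 9.96 ± 0.80 in mdx sln+/- (SD). The short transcript Dmd-201, with 18 exons at the 3' end, had 15.7 ± 4.90, 5.35 ± 0.46 and 5.35 ± 0.47 (SD). It lies within Dmd-203 on the same strand and can share reads with it, so whether Dmd-201 itself is lower is uncertain. The level of Sln was not analysed here, so the loss of its allele was not checked against the labels.

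**Figure D1:**
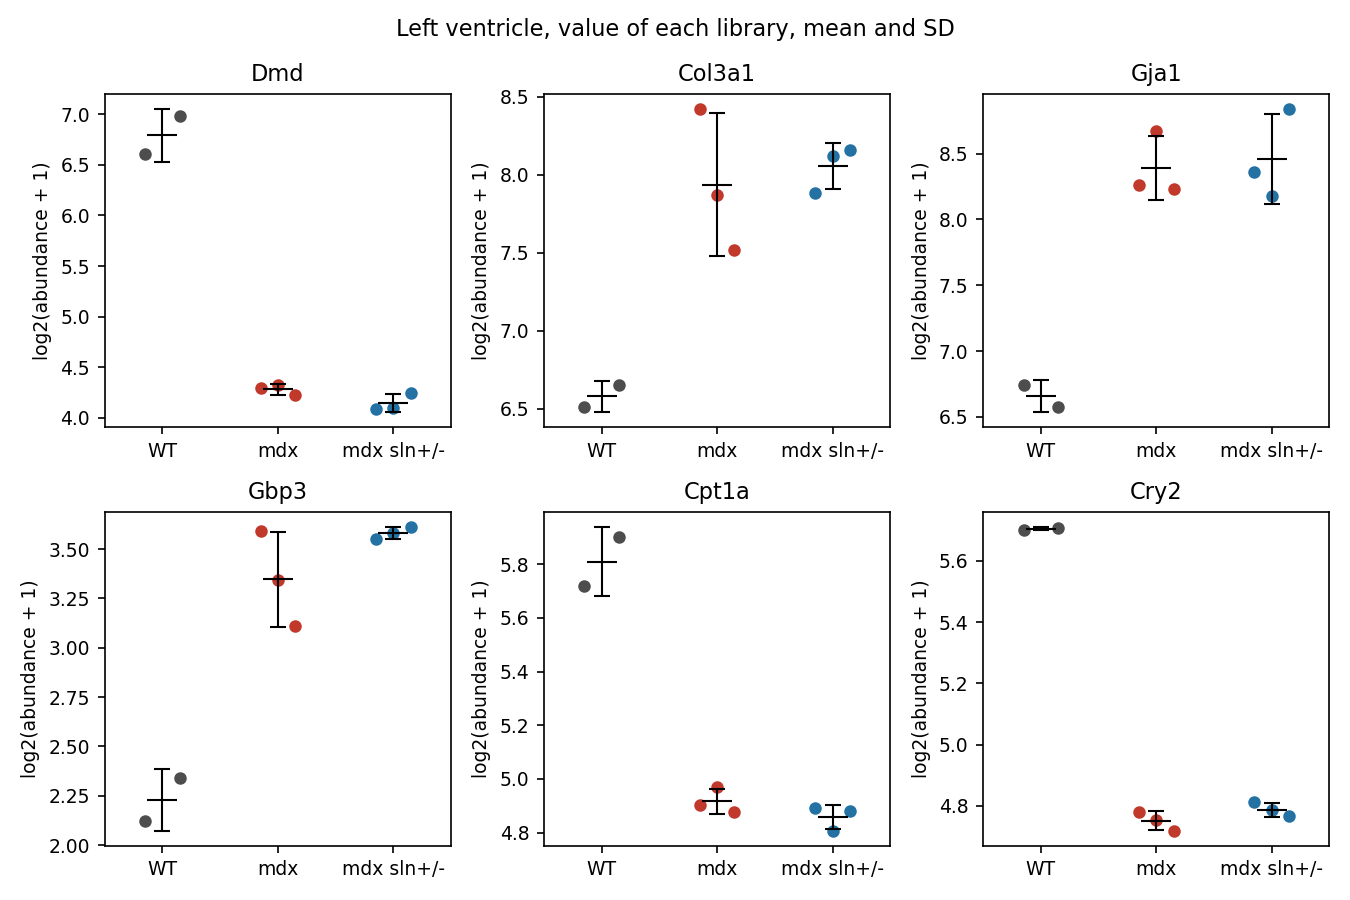
Log2(abundance + 1) of 6 genes in the 8 libraries, with 1 point per library and the group mean with its SD as a bar; each panel has its own axis, which does not start at 0. All 6 libraries of the mdx groups lie below both WT libraries for Dmd (log2 change of mdx against WT -2.51), Cpt1a (-0.89) and Cry2 (-0.95), and above them for Col3a1 (1.36), Gja1 (1.73) and Gbp3 (1.12).

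Between mdx and WT, the gene lists of matrix, interferon response, immediate early response and macrophages were called higher, and those of the circadian clock, fatty acid oxidation and antioxidant defence lower. None of these 7 list calls held with an estimated correlation, where the smallest adjusted p of any list was 0.118, and 21 of the 30 fatty acid oxidation genes did not pass. Among matrix genes, fibrillin 1 (Fbn1), a microfibril protein, rose by 1.15 ± 0.11, the collagen Col15a1 by 1.08 ± 0.14, the fibrillar collagen Col3a1 by 1.36 ± 0.23 and Timp1, an inhibitor of matrix proteases, by 1.84 ± 0.35. Cpt1a, which carries fatty acids into mitochondria, fell by 0.89 ± 0.07, and the mitochondrial carrier Ucp3 fell by 1.89 ± 0.17. The clock repressor Cry2 fell by 0.95 ± 0.05. The gap junction gene Gja1 (connexin 43) rose by 1.73 ± 0.20. In limma, 3798 of the 13783 genes passed an adjusted p of 0.05, 2045 higher and 1753 lower, and 365 of these changed over 2-fold, 191 higher and 174 lower. At an unadjusted p of 0.05, 5661 genes passed, where chance gives 689 if p-values are not too small, as those of the group fit are. With median-ratio scaling 1851 genes were higher and 1968 lower, so the larger side turned.

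The size of that count rests on how the values had been prepared. A term that parts mdx 2 and mdx sln+/- 2 from the other mdx and mdx sln+/- libraries had been removed from the values, so 1 of 5 residual degrees of freedom was already used. With this term fitted, 2080 genes were called, 1123 higher and 957 lower, all of them among the 3798. The library names come in 2 styles, indexed and plain, and all WT libraries have plain names. With name style as a term 1554 genes were called (853 higher, 701 lower), and with only plain-named libraries, 2 WT against mdx 3, 122 (63 higher, 59 lower), with 1 residual degree of freedom that comes from WT alone. Without WT 2 the count was 2373, and with only the libraries of these 2 groups fitted it was 2015. Y-linked genes differed within the WT group, with Eif2s3y at a log2 level of 6.11 in WT 1 and 0.92 in WT 2. Without WT 2 and mdx sln+/- 3, the libraries with the lowest Y-linked levels, 1685 genes were called (912 higher, 773 lower). For 7081 genes (51.4%) no WT library overlapped an mdx library, where chance gives 20% for exchangeable libraries. The removed term draws mdx 2 towards the other mdx and mdx sln+/- libraries, so the share without an effect lies above 20%.

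By the rule for named genes, the largest rises were those of Tmprss13, a transmembrane serine protease (3.81 ± 0.10, 14.1-fold, adjusted p = 1.66e-06), Egr1, an immediate early transcription factor (3.18 ± 0.60), and H2-Ab1, a chain of an MHC class II molecule (3.05 ± 0.33). Next came Gcnt1, a glycosyltransferase (2.96 ± 0.14), H2-Eb1, another class II chain (2.82 ± 0.32), and Hsd17b7, an enzyme of cholesterol synthesis (2.77 ± 0.14). The largest falls beside Dmd were those of Atcayos (-2.74 ± 0.07), Cntn2, a cell adhesion protein found in the conduction system of the heart (-2.69 ± 0.35), Rps13-ps2 (-2.41 ± 0.10), Dixdc1 (-2.34 ± 0.09) and Dusp18 (-2.22 ± 0.09). Tmprss13 lies on chromosome 9 from 45319100 to 45347581, plus strand, and overlaps 1700003G13Rik on the other strand. Gcnt1 lies on chromosome 19 from 17326141 to 17372844, minus strand, and Dixdc1 on chromosome 9 from 50662752 to 50739517, minus strand. Atcayos is an antisense RNA overlapping Atcay and Nmrk2 on chromosome 10 (81194609 to 81210877), and whether the counting used strand is not given, so its value is uncertain. Rps13-ps2 is a processed pseudogene (chromosome 7, 88530446 to 88530898) that can share reads with Rps13. Its change was -1.24 in the r2 columns alone, where it was not called (adjusted p = 0.385). The call of Egr1 ended without WT 2 (adjusted p = 0.0579), and with only plain-named libraries those of Egr1 and Cntn2 ended.

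**Figure D2:**
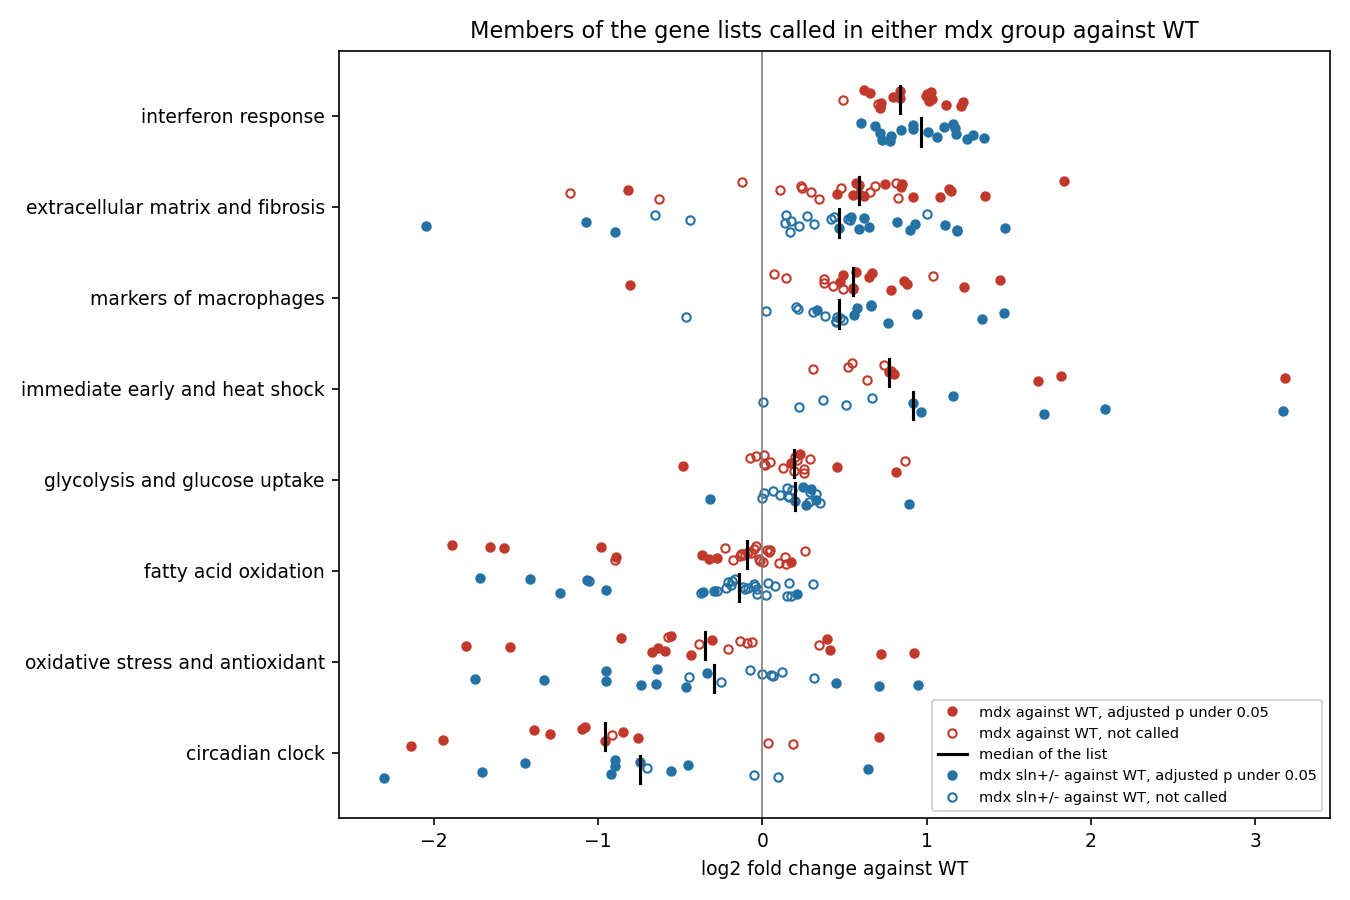
Log2 fold change against WT of each measured member of 8 gene lists, with mdx above mdx sln+/- in each list, filled points for an adjusted p under 0.05, open points for genes not called and black bars for the median of each list. Median changes of mdx against WT are 0.84 for the interferon response, 0.59 for matrix, 0.55 for macrophage markers, 0.77 for immediate early genes, 0.19 for glycolysis, -0.09 for fatty acid oxidation, -0.35 for antioxidant genes and -0.95 for clock genes.

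Gene lists were tested with limma's camera at a preset correlation of 0.01, and of the 31 lists 26 had at least 3 measured members. In mdx against WT 7 lists passed, 4 higher and 3 lower. With an estimated correlation no list call held in any of the 3 comparisons. By fry 6 lists were called: matrix (adjusted p = 0.0512) and fatty acid oxidation (0.118) were not, and glycolysis was (0.00858). Of the 29 measured matrix and fibrosis genes 15 rose, 1 fell (Lox, an enzyme that crosslinks collagen) and 13 did not pass. Adjusted over the list alone 17 rose and 1 fell (adjusted p = 1.58e-04; adjusted p = 0.805 with an estimated correlation). Of 18 interferon response genes 16 rose and none fell, 18 adjusted over the list alone. The list held Oasl2 at 1.00 ± 0.12, the guanylate-binding protein Gbp3 at 1.12 ± 0.14 and Ifit1 at 1.22 ± 0.18 (adjusted p = 3.93e-08; adjusted p = 0.444 with an estimated correlation). Of 11 immediate early and heat shock genes 5 rose (Atf3, Egr1, Fos, Hspa1a and Hspa1b), 8 adjusted over the list alone. The list held the stress transcription factor Atf3 at 1.68 ± 0.21 (adjusted p = 0.00145; adjusted p = 0.444 with an estimated correlation).

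Of 20 macrophage markers 12 rose and 1 fell (Cd163, a scavenger receptor of resident macrophages), 13 and 1 adjusted over the list alone. Among these, the integrin Itgam rose by 0.65 ± 0.10, the chemokine receptor Ccr2 by 1.23 ± 0.20 and Cx3cr1 by 1.45 ± 0.29 (adjusted p of the list = 1.75e-04; adjusted p = 0.771 with an estimated correlation). Of 13 circadian clock genes 9 fell, 1 rose (the activator Npas2, 0.71 ± 0.13) and 3 did not pass, 9 and 2 adjusted over the list alone. The falls included Cry2, the nuclear receptor Nr1d2 (-1.29 ± 0.07) and Dbp, a transcription factor driven by the clock (-1.94 ± 0.18; adjusted p of the list = 5.25e-05; adjusted p = 0.118 with an estimated correlation). Of 30 fatty acid oxidation genes 8 fell and 1 rose (Acads), the same numbers adjusted over the list alone, and 21 did not pass. The falls included the regulators Ppara (-0.98 ± 0.12) and Ppargc1a (-1.66 ± 0.21), beside Cpt1a and Ucp3 (adjusted p of the list = 0.0211; adjusted p = 0.805 with an estimated correlation). Of 20 genes of oxidative stress and antioxidant defence 9 fell and 4 rose, 10 and 4 adjusted over the list alone. Gclc, of glutathione synthesis, fell by 0.67 ± 0.07, the thioredoxin reductase Txnrd1 by 0.55 ± 0.07 and the metallothionein Mt2 by 1.80 ± 0.37. Cybb and Cyba, subunits of the phagocyte NADPH oxidase, rose by 0.92 ± 0.12 and 0.72 ± 0.12 (adjusted p of the list = 0.0422; adjusted p = 0.444 with an estimated correlation).

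The lists of fatty acid oxidation and of oxidative stress and antioxidant lost their calls without WT 2 (adjusted p = 0.336 and 0.197) and without both low Y-linked libraries (0.296 and 0.157). Fatty acid oxidation also lost it without mdx 1 (0.0937) and with name style as a term (0.0688), with Eif2s3y as a term (0.139) and in the r1 columns alone (0.071). The antioxidant list also lost it with Eif2s3y as a term (0.0812), with median-ratio scaling (0.0507) and in the r2 columns alone (0.0512). Without WT 1 the number of called lists rose from 7 to 12. The call of Mt2 ended without WT 2 (adjusted p = 0.072) and that of Cx3cr1 with name style as a term (0.0545).

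Of 17 genes of cardiac stress and the fetal programme 7 rose, 1 fell and 9 did not pass (8 and 1 adjusted over the list alone), and the list was not called (adjusted p = 0.0642). The natriuretic peptide Nppb rose by 1.84 ± 0.35, the slow myosin heavy chain Myh7 by 1.42 ± 0.24 and the calcineurin regulator Rcan1 by 1.54 ± 0.23, whereas skeletal alpha-actin (Acta1) fell by 1.34 ± 0.26. The call of Nppb ended without WT 2 (adjusted p = 0.0599). Of 21 cardiac ion channel genes 3 rose and 6 fell (4 and 7 adjusted over the list alone; list adjusted p = 0.403). They included Gja1, the potassium channel Kcnj2 (-0.84 ± 0.11), the sodium channel subunit Scn4b (-1.89 ± 0.25) and Kcne1 (-2.18 ± 0.33). Of 27 calcium handling genes 4 rose and 3 fell, 6 and 3 adjusted over the list alone. The calcium channel subunit Cacnb2 rose by 0.78 ± 0.07, and the ryanodine receptor Ryr2 and the SERCA inhibitor Pln were among the genes that fell. The median of this list (-0.02) and its mean (0.01) differ in sign (list adjusted p = 0.977). Of 19 genes of the dystrophin-associated complex 2 rose and 4 fell, likewise adjusted over the list alone, with the dystrobrevin Dtna at -0.43 ± 0.05 and the syntrophin Sntb1 at 1.05 ± 0.14 (list adjusted p = 0.324). Of 20 sarcomere genes 4 rose and 2 fell, likewise adjusted over the list alone, with desmin (Des) at 0.50 ± 0.09 and Myom2 at 0.44 ± 0.09 (list adjusted p = 0.324). The call of Myom2 ended without WT 2 (adjusted p = 0.0506).

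Of 19 genes of glycolysis and glucose uptake 4 rose and 1 fell (5 and 1 adjusted over the list alone; list adjusted p = 0.0642). Examples are enolase 1 (Eno1) at 0.82 ± 0.08 and hexokinase 2 (Hk2) at -0.48 ± 0.08. Of 28 nuclear genes of oxidative phosphorylation 1 rose (Cox6a2, 0.21 ± 0.06, which overlaps Itgad) and 1 fell (Sdhc, -0.27 ± 0.06), 0 adjusted over the list alone (list adjusted p = 0.967). Of 12 cell cycle genes 3 rose and 1 fell, likewise adjusted over the list alone (list adjusted p = 0.0642). Examples are the replication helicase subunit Mcm6 at 1.86 ± 0.21 and Cdk1 at 0.85 ± 0.21. Of 17 genes of the unfolded protein response 3 rose and 3 fell (5 and 3 adjusted over the list alone; list adjusted p = 0.778). Examples are the chaperones Dnajc3 at -0.47 ± 0.05 and Dnajb9 at -0.77 ± 0.09. Of 18 genes of autophagy and proteolysis 1 rose and 3 fell, likewise adjusted over the list alone (list adjusted p = 0.324). Examples are the kinase Ulk1 at -0.48 ± 0.05 and Bnip3 at -0.65 ± 0.09. With the removed term fitted, the calls of Sdhc, Cox6a2 and Cdk1 ended (adjusted p = 0.0552, 0.103 and 0.0506). The call of Cox6a2 ended without each library except mdx 3 (adjusted p up to 0.0815, without mdx 2), that of Sdhc without WT 1 (0.0612) and that of Cdk1 without WT 1 (0.0572) or WT 2 (0.097).

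No other list of cell type markers was called. Of 12 endothelial markers 4 rose and 3 fell, likewise adjusted over the list alone, with Emcn at 0.34 ± 0.05 and von Willebrand factor (Vwf) at -1.20 ± 0.25 (list adjusted p = 0.48). Of 9 markers of smooth muscle and pericytes 2 rose and 0 fell, likewise adjusted over the list alone (Notch3, 0.57 ± 0.13, and Rgs5, 0.65 ± 0.16; list adjusted p = 0.422). Of 11 fibroblast markers 0 passed, 0 adjusted over the list alone (list adjusted p = 0.967). Of 9 atrial markers 1 rose (Gja5, 0.45 ± 0.07) and 1 fell (Stard10, -0.83 ± 0.21), 2 and 2 adjusted over the list alone (list adjusted p = 0.475). Of 3 markers of neutrophils and mast cells the mast cell protease Mcpt4 rose by 0.75 ± 0.22 (1, or 2 adjusted over the list alone; list adjusted p = 0.324). Of 4 nerve and Schwann cell markers Kcna1 fell by 0.59 ± 0.15 (1, or 3 adjusted over the list alone; list adjusted p = 0.0819). Of 5 blood markers and of 4 Y-linked genes in the sex-linked list 0 passed, 0 adjusted over the list alone (list adjusted p = 0.509 for each). Of 5 RNAs without a poly(A) tail the histone gene Hist1h4h fell by 0.52 ± 0.07, likewise adjusted over the list alone (list adjusted p = 0.509). The lists of lymphocytes, skeletal muscle, adipocytes and mesothelium had 1 measured member each and were not tested. Ighm rose by 0.70 ± 0.17 and Plin4, which overlaps Hdgfl2, fell by 1.18 ± 0.22. Mybpc2 (0.41 ± 0.21) and Wt1 (0.63 ± 0.21) did not pass over all genes. As lists of 1, Wt1 passed and Mybpc2 did not. The mitochondrially encoded genes had 0 measured members. Without WT 2 the change of Vwf was -0.77 and that of Rgs5 was 0.38. Calls that ended with 1 library left out were Ighm (WT 1 0.06, WT 2 0.0788), Notch3 (WT 2 0.0956), Rgs5 (WT 2 0.114, mdx 1 0.055, mdx 3 0.0544), Stard10 (WT 1 0.06, WT 2 0.119), Plin4 (WT 2 0.0535) and Mcpt4 (all but WT 2 and mdx 3, up to 0.184 without WT 1). The calls of Mcpt4, Rgs5, Stard10 and Kcna1 also ended with the removed term fitted (adjusted p = 0.0843, 0.0529, 0.0532 and 0.0656).

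No gene passed in mdx sln+/- against mdx, the comparison that asks what losing 1 Sln allele changes. In limma 0 of 13783 genes had an adjusted p under 0.05, and the smallest was 0.117. At an unadjusted p of 0.05, 1886 genes passed, where chance gives 689 if p-values are not too small, as those of the group fit are. Genes are also not independent, so the excess over 689 does not measure an effect. With the removed term fitted the numbers were 0 called genes, a smallest adjusted p of 0.477 and 1186 genes at the unadjusted threshold. Within the indexed libraries 0 genes were called (2540 unadjusted), and within the plain-named ones, 1 against 1, also 0 (463 unadjusted), where the 2 WT libraries alone supply the spread, so that this last count says little. With the leading transcript in place of the sum over transcripts, 1 gene was called, the prostaglandin synthase Ptgds (adjusted p = 0.0202). The groups did not overlap in 3414 genes (24.8%), where chance gives 10% for exchangeable libraries. The removed term sets mdx 2 and mdx sln+/- 2 on opposite sides of the mean of the others, so the share without an effect lies above 10%. Dmd differed by -0.14 ± 0.10 (adjusted p = 0.57).

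The genes with the smallest p-values are given as values only. Higher in mdx sln+/- were Tob2 (0.45 ± 0.06), the mitochondrial carrier Slc25a25 (0.45 ± 0.06), Tmem86a (0.35 ± 0.05) and Psd (0.49 ± 0.07). Lower were Zbed6 (-0.83 ± 0.09), the chemokine Ccl2 (-0.85 ± 0.10), Ptgds (-0.63 ± 0.08) and the processed pseudogene Amd-ps3 (-0.69 ± 0.09). Their adjusted p-values were 0.117 to 0.122. Zbed6 (chromosome 1, 133655879 to 133660885, minus strand) lies within Zc3h11a on the same strand, and Amd-ps3 (chromosome 18, 64448685 to 64449689) can share reads with its parent gene, so their values are uncertain.

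**Figure D3:**
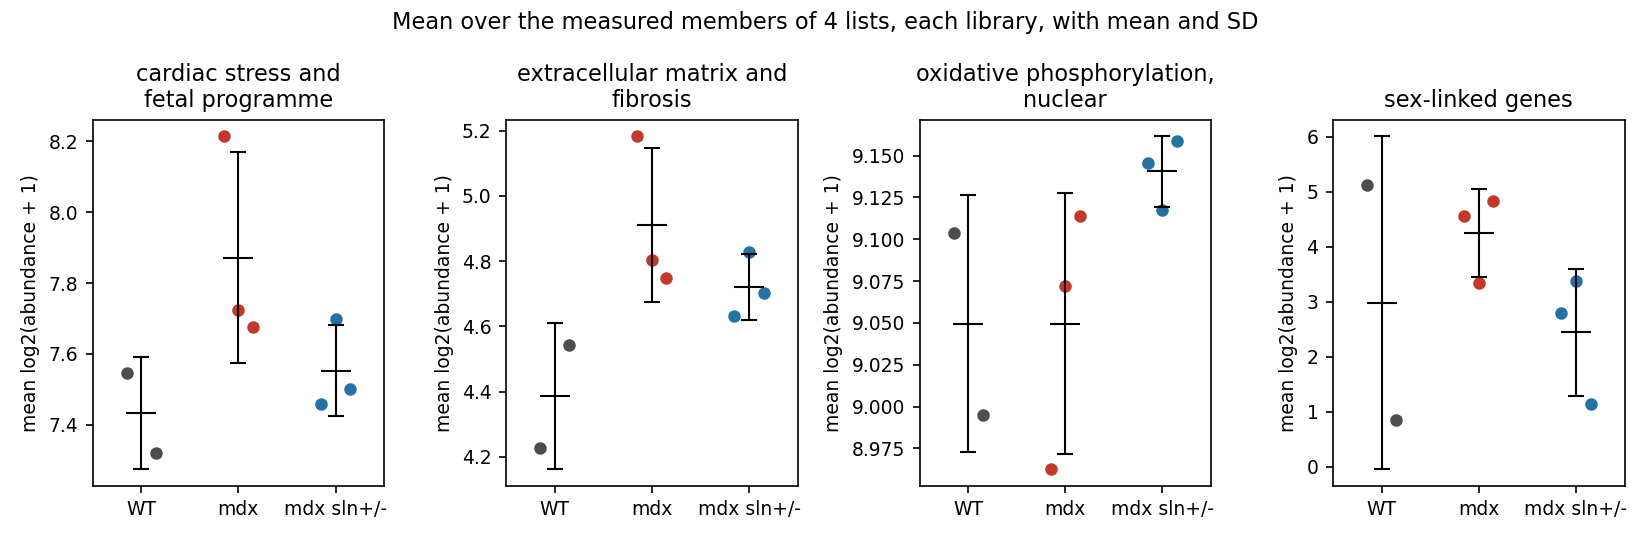
Mean log2(abundance + 1) over the measured members of 4 gene lists in each library, with 1 point per library and the group mean with its SD as a bar; axes do not start at 0. For cardiac stress genes mdx 1 lies at 8.21 and the other mdx libraries at 7.73 and 7.68, beside 7.46, 7.70 and 7.50 in mdx sln+/-.

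Among the gene lists, 4 differed between mdx sln+/- and mdx in camera, although none of their members passed over all genes. Every other split of these 6 libraries into 3 against 3 called at least as many lists, 4 to 12, so 4 is not more than regrouping gives. Genes of cardiac stress and the fetal programme were lower in mdx sln+/-, with 16 of 17 negative and a median of -0.32 (adjusted p = 8.35e-08; adjusted p = 0.887 with an estimated correlation). Adjusted over the list alone 5 of them passed in the group fit, all lower. They were Xirp1 (-0.30 ± 0.07) and Xirp2 (-0.53 ± 0.15), actin-binding repeat proteins, Fhl1 (-0.45 ± 0.12), Clu (-0.26 ± 0.06) and the cytokine receptor Tnfrsf12a (-0.84 ± 0.23). This adjustment does not correct over the lists, and the p-values of the group fit are too small. Of 29 matrix and fibrosis genes 20 were lower, with a median of -0.18 and 0 adjusted over the list alone (adjusted p = 9.93e-04; adjusted p = 0.887 with an estimated correlation). Of 28 nuclear oxidative phosphorylation genes 27 were higher, with a median of 0.09 and 0 adjusted over the list alone. Ndufa4 had the smallest p (0.26 ± 0.06; adjusted p of the list = 0.0046; adjusted p = 0.887 with an estimated correlation). The 4 Y-linked genes were all lower, with a median of -1.79 and 0 adjusted over the list alone (adjusted p = 0.029; adjusted p = 0.887 with an estimated correlation). Eif2s3y ranged from 5.91 in mdx 1 to 4.01 in mdx 2 and from 4.14 in mdx sln+/- 2 to 1.31 in mdx sln+/- 3.

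Without mdx 1 the mean change of the cardiac stress list went from -0.32 to -0.15, still called (adjusted p = 2.92e-04), that of matrix from -0.19 to -0.06 and that of oxidative phosphorylation from 0.09 to 0.05, a value it also had with median-ratio scaling. The mean of the Y-linked genes went from -1.80 to -1.15 without mdx sln+/- 3, and was -0.86 within the indexed and -3.69 within the plain-named libraries. With only plain-named libraries the mean of the cardiac stress list was -0.17, and with Eif2s3y as a term -0.19. The matrix and oxidative phosphorylation lists lost their calls without mdx 1 (adjusted p = 0.35 and 0.169) and with only plain-named libraries (0.6 and 0.558). The sex-linked list lost it without mdx 1 (0.0755), mdx 3 (0.177) or mdx sln+/- 3 (0.2) with median-ratio scaling (0.117), upper-quartile scaling (0.0742), rescaling without mitochondrial copies (0.0627) and with Eif2s3y as a term (0.967). In mdx 1 the transcripts taken as nuclear copies of mitochondrial genes held 23.7% of the abundance, the lowest share, against up to 33.4% in mdx 3. These can share reads with the mitochondrial genes, which have 0 rows of their own, so the share does not measure nuclear copies alone. The retained-intron transcripts of mdx 1 held 2.92%, the highest share. The other 22 tested lists were not called by camera (adjusted p = 0.202 to 0.986). By fry, which asks whether members move one way, the circadian clock was the single called list (adjusted p = 0.00857). Adjusted over the list alone, Per1 (0.40 ± 0.06) and Nr1d2 (0.39 ± 0.06) of the clock list were higher. So were Ulk1 (0.23 ± 0.04) and the ubiquitin ligase Fbxo32 (0.43 ± 0.09) of the autophagy list and the glucose transporter Slc2a1 (0.33 ± 0.07) of the glycolysis list. None of these passed over all genes.

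In mdx sln+/- against WT the 7 lists called in mdx against WT were called, and glycolysis as well, though none held with an estimated correlation. Dmd fell by 2.65 ± 0.11 (adjusted p = 1.97e-05). All 18 measured interferon response genes rose, such as Oasl2 (1.17 ± 0.12), Gbp3 (1.35 ± 0.14) and Ifit1 (1.28 ± 0.18). Cpt1a fell by 0.95 ± 0.07, Cry2 by 0.92 ± 0.05 and Acta1 by 1.96 ± 0.26, and Gja1 rose by 1.80 ± 0.20. In limma 3996 genes were called, 2419 higher and 1577 lower, and 364 changed over 2-fold (208 higher, 156 lower). At an unadjusted p of 0.05, 5879 genes passed, where chance gives 689 if p-values are not too small, as those of the group fit are. The groups did not overlap in 8247 genes (59.8%), where chance gives 20% for exchangeable libraries. The removed term draws mdx sln+/- 2 towards the other libraries, so the share without an effect lies above 20%.

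With median-ratio scaling 1814 genes were higher and 2047 lower, so the share of higher genes moved from 60.5% to 47.0%. With the removed term fitted 2193 genes were called (1297 higher, 896 lower), all of them among the 3996. With name style as a term 1795 were called (1092 higher, 703 lower), and with only plain-named libraries 333 (163 higher, 170 lower). The count was 2161 without mdx sln+/- 1, 2530 without mdx sln+/- 2, 2506 without WT 2 and 1437 (838 higher, 599 lower) without the low Y-linked libraries WT 2 and mdx sln+/- 3.

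The largest rises were again Tmprss13 (3.51 ± 0.10), Gcnt1 (3.33 ± 0.14), Egr1 (3.17 ± 0.60), Hsd17b7 (2.90 ± 0.14), H2-Ab1 (2.86 ± 0.33) and H2-Eb1 (2.68 ± 0.32). The largest falls beside Dmd were Fkbp5, a glucocorticoid-induced co-chaperone (-2.72 ± 0.69), Atcayos (-2.60 ± 0.07), Rps13-ps2 (-2.51 ± 0.10), Amd-ps3 (-2.36 ± 0.10) and Angptl7 (-2.32 ± 0.48), which lies within Mtor on the other strand. The call of Fkbp5 ended with the removed term fitted (adjusted p = 0.0503), without WT 1 (0.0634) and without WT 2 (0.113), that of Egr1 without WT 2 (0.0569), that of Angptl7 with name style as a term (0.053) or without the low Y-linked libraries (0.0534) and that of Rps13-ps2 in the r2 columns alone (0.33). Without WT 2 the change of Angptl7 was -1.36, still called.

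In this comparison 8 lists were called. By fry 7 were called: matrix and fatty acid oxidation were not (adjusted p = 0.125 each), and RNA without a poly(A) tail was (0.0419). Matrix and fibrosis had 12 of 29 genes higher and 3 lower (13 and 3 adjusted over the list alone). They included Col3a1 (1.48 ± 0.23), Col15a1 (1.18 ± 0.14) and Fbn1 (0.93 ± 0.11; adjusted p of the list = 0.0262; adjusted p = 0.949 with an estimated correlation). The interferon response had 18 adjusted over the list alone (adjusted p = 7.1e-08; adjusted p = 0.414 with an estimated correlation). Immediate early genes had 6 of 11 higher, likewise adjusted over the list alone, with Atf3 at 1.71 ± 0.21 (adjusted p of the list = 0.0192; adjusted p = 0.414 with an estimated correlation). Macrophage markers had 9 of 20 higher and 0 lower (11 and 0 adjusted over the list alone). Examples are Lyz2 at 0.58 ± 0.08, Ccr2 at 1.34 ± 0.20 and Cx3cr1 at 1.47 ± 0.29 (adjusted p of the list = 0.00341; adjusted p = 0.949 with an estimated correlation). Clock genes had 9 of 13 lower and 1 higher (Npas2, 0.64 ± 0.13), likewise adjusted over the list alone. The falls included Nr1d2 at -0.90 ± 0.07 and Dbp at -1.70 ± 0.18 (adjusted p of the list = 3.15e-05; adjusted p = 0.108 with an estimated correlation). Fatty acid oxidation had 7 of 30 lower and 1 higher, likewise adjusted over the list alone. The falls included Ucp3 at -1.72 ± 0.17, Ppara at -1.07 ± 0.12 and Ppargc1a at -1.41 ± 0.21 (adjusted p of the list = 0.00475; adjusted p = 0.949 with an estimated correlation). Antioxidant genes had 9 of 20 lower and 3 higher (10 and 3 adjusted over the list alone). They included Gclc at -0.74 ± 0.07, Txnrd1 at -0.64 ± 0.07, Cybb at 0.95 ± 0.12 and Cyba at 0.71 ± 0.12 (adjusted p of the list = 0.0262; adjusted p = 0.414 with an estimated correlation). Glycolysis had 6 of 19 higher and 1 lower (7 and 1 adjusted over the list alone). The rises included Eno1 at 0.89 ± 0.08 and Hk1 at 0.33 ± 0.07 (adjusted p of the list = 0.0367; adjusted p = 0.414 with an estimated correlation).

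Several of these calls ended with 1 library left out. Without WT 1 the lists of matrix (adjusted p = 0.484) and immediate early genes (0.088) were not called, and the call of Hk1 ended (0.0605). Without WT 2 this held for fatty acid oxidation (0.115), glycolysis (0.0983) and the antioxidant list (0.0742). Matrix was also not called without mdx sln+/- 2 (0.0512), with name style as a term (0.119) or with Eif2s3y as a term (0.0654). Without both low Y-linked libraries fatty acid oxidation (0.0765), glycolysis (0.142) and the antioxidant list (0.0868) were not called. Glycolysis was not called without mdx sln+/- 3 (0.0681), and the call of Hk1 ended without mdx sln+/- 1 (0.0516). Of the lists not called (adjusted p = 0.0717 to 0.904), cardiac stress had 4 genes higher and 2 lower of 17, the ion channels 5 and 5 of 21 and calcium handling 6 and 2 of 27, likewise adjusted over the list alone. Their members included Rcan1 (1.17 ± 0.23), Scn4b (-2.15 ± 0.25) and Cacnb2 (0.65 ± 0.07), and the call of Rcan1 ended without WT 2 (adjusted p = 0.0638).

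Of the genes called in mdx against WT and in mdx sln+/- against WT, 2865 were called in both in the same direction (1630 higher, 1235 lower) and 0 in opposite directions. These comparisons share the 2 WT libraries, which are too few to give each comparison 2 of its own. Independent lists of these sizes would share 359 higher and 201 lower genes. Simulated libraries with no effect gave a mean of 0.18 shared calls over 100 draws, but as they call under 1 gene in each comparison they do not tell how much of the overlap comes from the shared WT libraries. The count was 1753 without mdx sln+/- 1, 1762 without WT 2, 1547 with the removed term fitted, 1160 with name style as a term and 1092 without the low Y-linked libraries. Across genes, which are not independent replicates, the log2 fold changes correlated at 0.915 (simulated 0.635 with no effect, from the shared WT libraries alone), and their covariance was 0.143 against a simulated 0.0145, a difference of 0.128.

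Whether genes that differ between mdx and WT move back in mdx sln+/- was asked with the covariance of the changes of mdx against WT and of mdx sln+/- against mdx. It was -0.0147, where the shared mdx libraries alone gave -0.00833 ± 0.000476 (SD of 100 simulated draws), a difference of -0.00636. The simulation drew each gene independently, with the spread that limma had shrunk. Its SD is thus too small and its mean may lie too near no covariance, so the difference does not decide. Without mdx 1 the covariance was -0.00601 and without mdx 3 it was -0.031, with no simulated value for these sets. Of the 3798 genes called in mdx against WT, 2322 (61.1%) had the opposite sign in mdx sln+/- against mdx. In the simulated libraries, which call too few genes for this, the share was 81.4% of genes with an unadjusted p under 0.05. These shares thus rest on differently chosen genes and are not the same measure. The correlation of the changes in mdx against WT and in mdx sln+/- against mdx was -0.227 against a simulated -0.426. These simulated libraries hold no mdx effect. A real mdx effect that mdx sln+/- leaves unchanged brings the share and the correlation nearer to no relation than in them, so neither decides. Whether genes move back thus stays open. In a principal component analysis the first component (57.8% of the variance) parted the WT libraries, at 29.6 and 38.5, from all 6 mdx and mdx sln+/- libraries, at -6.74 to -18.0. The second component held 14.3%.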

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

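Beside the counts of calls, 166 gene results and 19 list results were followed through the alternatives. Of their values 4323 kept their direction and side of the threshold, 290 lost the call, 1 gained it and 2 changed sign. Of the counts and the covariance, 176 stayed near the main value and 28 moved. The bound for near was wide. In mdx against WT 10 called lists counted as near 7, and covariances of -0.031 and -0.00601 counted as near -0.0147. Counts of 0 in both settings also counted as near. The settings with the largest numbers of losses were only plain-named libraries (81) and the low Y-linked libraries left out (48), which have fewer samples. The sign changes were Dmd in mdx sln+/- against mdx, uncalled, at 0.0219 with only plain-named libraries (-0.14 in the full fit) and the sex-linked list in the same comparison at 0.0754 with Eif2s3y as a term, which that term by construction takes up. With an estimated correlation 0 lists were called in mdx against WT, 0 in mdx sln+/- against mdx and 0 in mdx sln+/- against WT, and fry called 1 in mdx sln+/- against mdx. Fitting only the 2 groups gave 2015 calls in mdx against WT, where the full fit gave 3798. With as few samples it gave 3803 in mdx sln+/- against WT, where the full fit gave 3996. Name style as a term gave 1554 calls in mdx against WT, 1795 in mdx sln+/- against WT and an overlap of 1160. Only plain-named libraries gave 122 and 333, and 7 lists in mdx sln+/- against mdx. The removed term gave 2080, 2193 and an overlap of 1547, with 1 degree of freedom fewer. Without the low Y-linked libraries it was 1685, 1437 and 1092. The leading transcript gave 1 call in mdx sln+/- against mdx. For the other moved values the cause was not tested.

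With each library left out in turn, calls ranged from 2373 to 3570 in mdx against WT, 0 to 0 in mdx sln+/- against mdx and 2161 to 4473 in mdx sln+/- against WT, lists from 5 to 12, 3 to 5 and 6 to 9, the overlap from 1753 to 2865 and the covariance from -0.031 to -0.00601. Where this leaves WT with 1 library, that library is assumed to vary like the other groups.

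With a replicate block, the counts were 2397 in mdx against WT and 2363 in mdx sln+/- against WT, and the overlap 1731. The deviations of same-numbered libraries correlated as follows (mdx with mdx sln+/- -0.264, -0.996 and -0.311; WT with mdx 0.148 and 0.18; WT with mdx sln+/- -0.00452 and -0.18). The removed term forces the negative value of mdx 2 with mdx sln+/- 2 and takes out any shift they shared, so these values do not settle whether the numbers pair the libraries, and the planned fit without the block was kept.

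Not run were the count-model tests, limma-voom and TMM factors, which need counts, and indexed-named libraries alone against WT, which has none. The planned filter of at least 1 in 2 libraries became the main one. The removed term, pseudocounts, leading transcript, r1 and r2, a mean of 5, rescaling and Y-linked settings were added after the data were seen. Depth is unknown, so what it limits was not tested.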

Other observations

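Genes of MHC class II antigen presentation rose in both mdx groups; they form no planned list, were chosen after their values were seen and were not tested as a group. In mdx against WT, H2-Aa rose by 2.65 ± 0.28, H2-Ab1 by 3.05 ± 0.33, H2-Eb1 by 2.82 ± 0.32, the invariant chain Cd74 by 2.52 ± 0.30 and H2-DMa, which helps to load peptides, by 1.79 ± 0.23. The immunoproteasome subunits Psmb8 and Psmb9 rose by 1.38 ± 0.22 and 1.56 ± 0.28, and Ciita, the transactivator of class II genes, by 1.42 ± 0.30. The MHC class I genes H2-K1, H2-Q7 and H2-Q6 rose as well, by 1.60, 1.71 and 1.61 in mdx against WT. In mdx sln+/- against WT they rose by 1.56, 1.77 and 1.75, so the rise was not particular to class II. Ciita was not called without WT 1 (limma, adjusted p = 0.0521) or WT 2 (0.0523), nor with name style as a term (0.0646), and Psmb8 and Psmb9 were not called without the low Y-linked libraries (0.0569 and 0.066).

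H2-Aa lay at a log2 level of 4.21 and 4.19 in WT, 7.44, 6.50 and 6.62 in mdx, and 6.60, 7.07 and 6.46 in mdx sln+/-. In mdx sln+/- against WT it rose by 2.51 ± 0.28, Cd74 by 2.38 ± 0.30 and H2-DMa by 1.62 ± 0.23. Between mdx sln+/- and mdx, H2-Aa differed by -0.15 ± 0.25 and was not called (limma, adjusted p = 0.831). Macrophages are among the cells that carry these genes, and 12 of 20 macrophage markers also rose in mdx against WT, so the share of such cells is not parted here from expression per cell.

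Of the tests that follow, those of linked segments and of list splits had their predictions written before their result was seen; all others, and leaving out the MHC pairs, were chosen afterwards. The other 3 against 3 splits of the mdx and mdx sln+/- libraries, 10 in all with the real one, cannot give a share under 0.05. For genes the real split called 0 and the highest other 1. At the unadjusted threshold the real split had 1886 and the highest other 1377. Splits with mdx 2 and mdx sln+/- 2 on the same side had 174, 4, 9 and 7. The removed term holds these down, while the real split parts the pair, so they are no fair comparison for it. For lists the real split of these 10 called 4 and every other one at least as many, with 12 the highest, which may point to a structure of the samples apart from genotype.

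The largest differences of both mdx groups from WT were weighed against linked chromosome segments that could differ between the mouse lines. Among the 100 genes with the largest differences there were 15 pairs within 1 Mb, not counting pairs of like-named family members, where 10000 random draws gave a median of 7 and a 95% point of 13 (permutation p = 0.0238). This met the prediction written beforehand. Without the MHC pairs of chromosome 17, a step chosen afterwards, there were 9. The random draws were not repeated without the MHC genes, so this test does not decide. For library name style, 100 genes were ranked anew on their changes in the indexed libraries. The slope of the changes in plain-named on those in indexed libraries, each against a WT library of its own, was 0.531 ± 0.0478 or 0.796 ± 0.0342. These values differ by which WT library went with which. Ranking on the indexed changes can lower the slope without any effect of name style. The errors are those of the slope over genes, not over samples. As the bound was 0.5, name style stays open as a part of the cause.

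The lower clock output genes in both mdx groups could come from a different time of collection, since the activators Clock and Npas2 move against the others over the day. Of these 2 only Npas2 was called, at 0.71 in mdx and 0.64 in mdx sln+/- against WT. The activator Arntl of the list was not measured. The mean of Clock and Npas2 lay 1.57 above that of the other 11 clock genes in mdx against WT and 1.34 in mdx sln+/- against WT (one-sided exact permutation p = 0.0128 each, the smallest that 78 arrangements allow). That fits collection time, but a genotype effect on the clock would give the same, and the 2 cannot be parted here. With a WT library of its own for each name style, the slope over the clock genes was 0.945 ± 0.0484 or 1.12 ± 0.159 (error of the slope over genes). Both lie above the bound of 0.5 that name style as the cause would stay under.

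Y-linked levels (Eif2s3y, Ddx3y, Uty and Kdm5d) differ between libraries, with Eif2s3y at 6.11 and 0.92 in WT, 5.91, 4.01 and 5.79 in mdx, and 3.29, 4.14 and 1.31 in mdx sln+/-. The removed term by construction sets the mean of mdx 2 and mdx sln+/- 2 to that of the other 4 libraries. The difference between mdx sln+/- 2 and mdx 2, 0.0494 ± 0.103 (SE over the Y-linked genes), does not tell where they lay before. For mdx sln+/- 1 the smaller of its mean differences from mdx 1 and mdx sln+/- 3 was 1.66 ± 0.256. This error is the SE over the Y-linked genes, which move together, and does not measure the spread between samples. A term that shifts these libraries alike cannot make such a difference. What keeps mdx sln+/- 1 between them stays open, and no biological explanation was tested. The sex of the animals and Xist of the sex-linked list were not analysed here. As Y-linked levels are uneven between the groups, the group comparisons can hold whatever sets these levels.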
